A study of Mus musculus with 9 samples.

How the data were processed

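RNA sequencing of total RNA was deposited for 9 libraries of mouse hepatoma cells, 3 each of control, FICZ and tryptamine. The labels give a dose of 10 nM for FICZ and 50 uM for tryptamine, and 6 h of treatment in every group. The treatment label of the controls reads untreated, while the treatment protocol names a vehicle control, so the text says control. The source label names Hepa 1 WT cells and the cell line label reads HC1C. The labels do not say whether the libraries of a group come from separate cultures or whether equal replicate numbers share a day.

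The deposited tables, 1 for each of the 3 pairs of groups, list 189660 transcripts. Per the file headers they hold counts of reads for each library, as whole numbers without normalization. The same tables hold the authors' p-values and adjusted p-values for each transcript, and the authors' log2 fold changes of the first over the second group. The submitters' processing notes name DESeq without a version. A further pair of deposited lists names genes with higher transcripts, each with the authors' mean log2 fold change and smallest p-value. The aligner, the counting rule, the genome build and the annotation are not given in the sources used here, so no coordinates are printed.

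Every count column was assigned to its library through the group letters of the table and the replicate number in its header. Each library occurs in several tables, and all 9 repeated columns compared were identical between tables. Reads appear to have been counted for every transcript that they overlap, though the counting rule is not given. Of the counted transcripts, 19.3% held the same counts as another transcript of their gene. A sum over transcripts gave 5.61 to 5.83 times the total used here. The transcript with the highest mean count therefore stands for each gene. The plan had named sums over transcripts first and this choice for tables that cannot be summed. Sums are given among the alternatives. Gene IDs were present for 162807 transcripts of 28932 genes, of which 18257 had a count in at least 1 library. Of 5653 transcript entries that name several loci, 928 were assigned to a gene through their RefSeq identifier. The 26853 transcripts without a gene ID held 3.56 to 4.23% of the counts and were left out of the gene tests. The Ugt1a genes share 1 locus in the tables, which appears as Ugt1a2.

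The groups, the comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined. All 9 libraries entered 1 fit in edgeR 4.0.16 under R 4.3.3, with TMM scaling, the filterByExpr filter, group as the only term and the quasi-likelihood test. The filter kept 12372 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen, or to have passed. Adjusted p-values of genes in the text come from this test unless another tool is named. Fold changes and 95% intervals come from the fit, and SE is the log2 fold change divided by the square root of F. Levels in CPM are edgeR's counts scaled to the effective library size, which is the total of the genes tested times the TMM factor, and their SD is over the 3 libraries of a group. Intervals on raw counts cover counting error only, since reads without molecular identifiers are not independent molecules.

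The 18 gene lists cover AhR target genes, the AhR complex and its cofactors, NRF2 target genes, tryptophan and monoamine metabolism, the ER stress and amino acid response, p53 targets, the cell cycle, hepatocyte genes, cholesterol synthesis, fatty acid and lipid metabolism, the circadian clock, the inflammatory response, immediate early and growth genes, the hypoxia response, other xenobiotic metabolism, and markers of fibroblasts and stellate cells, of blood and endothelial cells and of bile duct epithelium. A list needed at least 3 measured members, which 17 had. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. The Benjamini-Hochberg adjustment ran over the lists of a comparison. The plan also named limma's fry test as an addition, and its adjusted p-values are printed only where fry is named.

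Named genes are, in each comparison, up to 10 with the largest rise and 10 with the largest fall among those that passed, with a mean of at least 20 counts in the higher group and no overlap between the libraries of the groups. To these come 10 genes always named (Cyp1a1, Cyp1a2, Cyp1b1, Ahrr, Tiparp, Nqo1, Ahr, Arnt, Maoa and Maob) and up to 3 members of each list with the smallest p. After control replicate 3 was seen to stand apart, the first part of the rule was also applied to the fit without it. Genes outside this rule, among them Cpox, Gsdmd, Slc7a5, Nfe2l2 and Gclm, were chosen after their values were seen.

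The alternatives set out beforehand were DESeq2 1.42.0 size factors, its Wald test, no filter on low counts, a filter of at least 10 counts in every library of a group, a fit to the 6 libraries of a pair, a term for the replicate number, each library left out in turn, thresholds of 0.01 and 0.1, transcripts tested singly, and other settings of camera. Chosen after seeing the data were sums over transcripts, RefSeq transcripts alone, limma's voom with library quality weights, the removal of each library's length trend by lowess with a span of 0.3, and the list tests without control replicate 3 or with the length trend removed. The fit was tested on simulated data with known changes. The simulated libraries shared the same spread for each gene and held no trend with transcript length. More genes were changed in them than passed in the data, so the shares recovered need not hold for the real libraries. The fit recovered 19.4 to 32.8% of 1.5-fold changes, 71.6 to 76.1% of 2-fold changes and 93.9 to 95.5% of 4-fold changes over the 3 comparisons. Without control replicate 3 it recovered 61.2 to 80.6% of 1.5-fold changes. Of the calls in these simulations, 2.34 to 8.03% were of unchanged genes, and values above the nominal 5% arose for tryptamine against control in both fits and for FICZ against control without control replicate 3.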

Results

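Transcript levels were measured by RNA sequencing in mouse Hepa 1 WT hepatoma cells after 6 h with FICZ, tryptamine or neither. FICZ is a tryptophan photoproduct that binds the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor. Tryptamine is a monoamine derived from tryptophan, and the title of the series names it as a proligand of the AhR that depends on monoamine oxidases. Each group holds 3 libraries. The total counts over genes were 14783258, 14554765 and 11594786 in control replicates 1, 2 and 3, and 14173722, 16715843 and 14675985 in the FICZ replicates. They were 14744608, 12983752 and 15540220 in the tryptamine replicates. Between 11875 and 12288 genes had at least 10 counts in a library.

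Control replicate 3 stood apart from the other 8 libraries. Its log CPM correlated with theirs across genes at 0.954 to 0.960, while the lowest correlation among the others was 0.987. Genes with transcripts of up to 1000 nt were higher in it, by a median log2 difference of 0.67 over 1140 genes, and genes with transcripts over 6000 nt were lower, with a median of -0.85 over 1324 genes. Its Cyp1a1 level of 58.3 CPM lay between those of control replicates 1 and 2, at 63.9 and 55.4. The square root of the common dispersion was 0.156 with this library and 0.0748 without it, so the counts of genes that passed are also given without it.

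**Figure D1:**
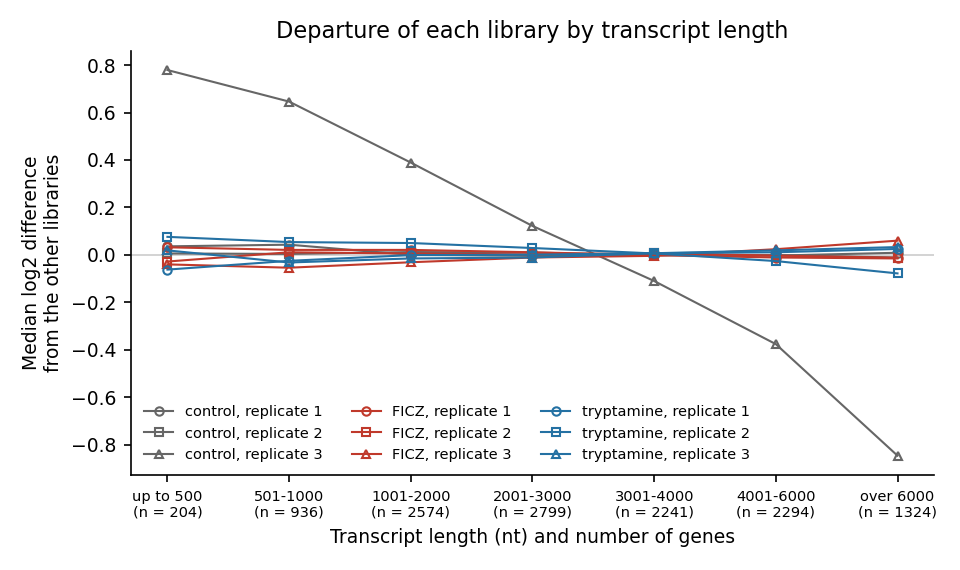
Median log2 difference of each library from the mean of the other libraries (vertical axis) by transcript length in nt (horizontal axis, with the number of genes in each class). Control replicate 3 was left out of that mean. Each library has 1 line, with colours for groups and symbols for replicates. Control replicate 3 falls from 0.78 in the shortest class to -0.85 in the longest, while the other libraries stay within -0.08 and 0.08.

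The comparison of FICZ with control asks which transcripts 10 nM of this AhR ligand changed within 6 h. Cyp1a1 (gene ID 13076), the cytochrome P450 most used as a readout of the AhR, rose 16.9-fold, from 59.2 ± 4.31 CPM (SD, n = 3) in control to 1002.8 ± 45.2 CPM (SD, n = 3). Other enzymes of xenobiotic and redox metabolism rose less. Xdh (gene ID 22436), xanthine dehydrogenase, rose 4.49-fold from 19.1 ± 7.14 to 86.4 ± 7.15 CPM, and Adh7 (gene ID 11529), an alcohol dehydrogenase, rose 2.31-fold from 60.6 ± 5.31 to 139.8 ± 2.65 CPM (SD, n = 3). Cyp1b1 (gene ID 13078), a cytochrome P450 of the same family as Cyp1a1, rose 3.35-fold, and Nqo1 (gene ID 18104), a quinone reductase, rose 2.48-fold. Slc2a6, a hexose transporter, rose from 0.465 ± 0.287 to 6.16 ± 0.942 CPM (SD, n = 3), a log2 change of 3.65 ± 0.505 (SE).

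With edgeR's quasi-likelihood test, 14 of 12372 genes rose and 0 fell. At an unadjusted p under 0.05, 435 genes were higher and 569 lower (642 and 608 without control replicate 3). If no gene changed, about 5% of the 12372 would lie under that threshold, and these 1004 are more. DESeq2's Wald test called 45 higher and 9 lower. The adjusted p was 5.03e-09 for Cyp1a1 (log2 4.08 ± 0.101, SE), 0.000658 for Adh7 (log2 1.21 ± 0.098, SE), 0.00506 for Tbc1d16 (log2 1.46 ± 0.151, SE), a protein with a Rab GTPase-activating domain, and 0.00539 for Xdh (log2 2.17 ± 0.233, SE). These 4 genes passed in each of the 9 fits that left out 1 library. The other 10 had adjusted p-values from 0.0147 to 0.0434 and passed in 1 to 6 of the 9 fits: Cpox (log2 1.00), an enzyme of heme synthesis, Mpp2 (1.27), Nqo1 (1.31), Cyp1b1 (1.74), Slc2a6, Cyp2s1 (0.95), Tnfaip2 (1.55), Tiparp (0.74), Gsdmd (0.63) and Arhgap10 (2.16). Cpox and Gsdmd lie outside the rule for named genes and were chosen after their values were seen. The count was 101 without control replicate 3, with 72 genes higher and 29 lower and all 14 genes kept. It was 5 and 8 without control replicates 1 and 2, 4 without each FICZ replicate, and 6 and 7 without tryptamine replicates 1 and 3, whose removal changes the estimate of the spread and the genes tested.

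Among the 10 measured AhR target genes, 6 rose with FICZ over all genes tested (Cyp1a1, Xdh, Cyp1b1, Nqo1, Cyp2s1 and Tiparp), and 9 rose when adjusted over the list alone. The list had a median log2 change of 1.13, with 10 of 10 members above 0 (camera adjusted p = 1.38e-75, and adjusted p = 5.99e-05 with an estimated correlation). Tiparp, a mono-ADP-ribosyltransferase induced by the AhR, rose from 33.3 ± 0.757 to 55.7 ± 3.86 CPM (SD, n = 3). Slc7a5, an amino acid transporter, had a log2 change of 0.03 ± 0.10 (SE, adjusted p = 0.906). In the fit without control replicate 3, 9 of the 10 members rose, which adds Aldh3a1 (log2 1.06 ± 0.085, SE), Nfe2l2 (0.40 ± 0.064, SE) and Cyp1a2.

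The list of NRF2 target genes, which respond to oxidative and electrophilic stress, had 1 of 16 measured members that rose, Nqo1, which the AhR list also holds. Adjusted over the list alone, 1 rose, and 2 rose over all genes and 8 over the list alone when control replicate 3 was left out. Its median log2 change was 0.14 with 12 of 16 members above 0 (camera adjusted p = 0.000579, and adjusted p = 0.0446 with an estimated correlation). Gclc, a subunit of the glutathione synthesis enzyme, had a log2 change of 0.44 ± 0.140 (SE), and Txnrd1, a thioredoxin reductase, 0.26 ± 0.093 (SE), each with an adjusted p of 0.601. None of 16 immediate early and growth genes passed over all genes. The median of this list was 0.13 with 13 of 16 above 0 (camera adjusted p = 0.0332, and adjusted p = 0.57 with an estimated correlation, at which the call is lost).

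Tryptamine was compared with control to see which transcripts 50 uM of the proposed proligand changed in the same time. Cyp1a1 rose 11.9-fold, from 59.2 ± 4.31 to 703.2 ± 44.0 CPM (SD, n = 3), and each tryptamine library lay above each control library. No other gene passed in the fit to all 9 libraries. Further AhR target genes were higher without passing in that fit. Cyp1b1 stood at 11.8 ± 2.82 CPM (SD, n = 3) against 4.29 ± 1.20 in control, Nqo1 at 56.3 ± 8.84 against 30.4 ± 6.98, and Xdh at 42.0 ± 2.96 against 19.1 ± 7.14 CPM (SD, n = 3).

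By edgeR's quasi-likelihood test, 1 of 12372 genes rose with tryptamine and 0 fell. Cyp1a1 had a log2 change of 3.57 ± 0.099 (SE, adjusted p = 1.66e-08) and passed in each of the 9 fits that left out 1 library. At an unadjusted p under 0.05, 270 genes were higher and 367 lower (449 and 376 without control replicate 3). The total of 637 with all 9 libraries is close to the 5% of genes that would lie there with no change. DESeq2's Wald test called 12 higher and 0 lower. Leaving out control replicate 3 gave 23 genes higher and 2 lower. In that fit Cyp1b1 rose by log2 1.24 ± 0.200 (SE, adjusted p = 0.00297), Nqo1 by 1.02 ± 0.134 (SE, adjusted p = 0.000187), Xdh by 0.85 ± 0.108 (SE, adjusted p = 0.000135) and Adh7 by 0.63 ± 0.078 (SE, adjusted p = 0.000126). Over 19 alternatives the adjusted p ranged from 3e-05 to 0.907 for Cyp1b1, from 0.000187 to 0.907 for Nqo1, from 0.000135 to 0.907 for Xdh and from 3.74e-08 to 0.865 for Adh7, and these genes passed in 5, 4, 4 and 4 of them. Txlnb (log2 1.30 ± 0.249, SE), Arhgap10 (1.96 ± 0.408, SE), Tnxb (0.57 ± 0.079, SE), Mpp2 (0.58 ± 0.112, SE) and Slc7a11 (0.71 ± 0.153, SE), the cystine transporter, also rose without that library. Loxl4 (log2 -0.29 ± 0.060, SE) and Lars2 (-0.81 ± 0.162, SE) fell there. Neither passed in any other of the 19 alternatives. Lars2 stood at 137 CPM in control replicate 2 against 74.2 and 49.1 in control replicates 1 and 3, and without control replicate 2 its log2 change was -0.033. Loxl4 stood at 331.4, 336.9 and 222.8 CPM in control replicates 1 to 3 and at 266.1 to 281.7 with tryptamine, so its fall depends on leaving out control replicate 3.

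Of the 10 measured AhR target genes, 1 rose with tryptamine over all genes tested and 8 rose when adjusted over the list alone. These counts were 6 and 9 without control replicate 3. The list's median log2 change was 0.69 with 10 of 10 members above 0 (camera adjusted p = 1.71e-49, and adjusted p = 0.000189 with an estimated correlation). Tiparp, at 46.4 ± 4.59 CPM (SD, n = 3), had a log2 change of 0.48 ± 0.111 (SE, adjusted p = 0.741) and passed in 0 of 19 alternatives, with a lowest adjusted p of 0.059. For NRF2 targets, 0 of 16 rose over all genes and 2 when adjusted over the list alone, Nqo1 and Slc7a11 (3 and 6 without control replicate 3). Their median was 0.22 with 13 of 16 above 0 (camera adjusted p = 6.08e-06, and adjusted p = 0.0153 with an estimated correlation). The 13 measured genes of cholesterol synthesis had a median of 0.25 with 12 of 13 above 0, and 0 passed over all genes or the list alone (0 and 1 without control replicate 3). The camera adjusted p of this list was 8.74e-05, and the adjusted p was 0.111 with an estimated correlation, at which the call is lost. Without control replicate 3 these values were 1.38e-05 and 0.0487. Idi1, which isomerises isopentenyl diphosphate, had a log2 change of 0.51 ± 0.205 (SE), and Sqle, squalene epoxidase, 0.22 ± 0.084 (SE), each with an adjusted p of 0.741.

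**Figure D2:**
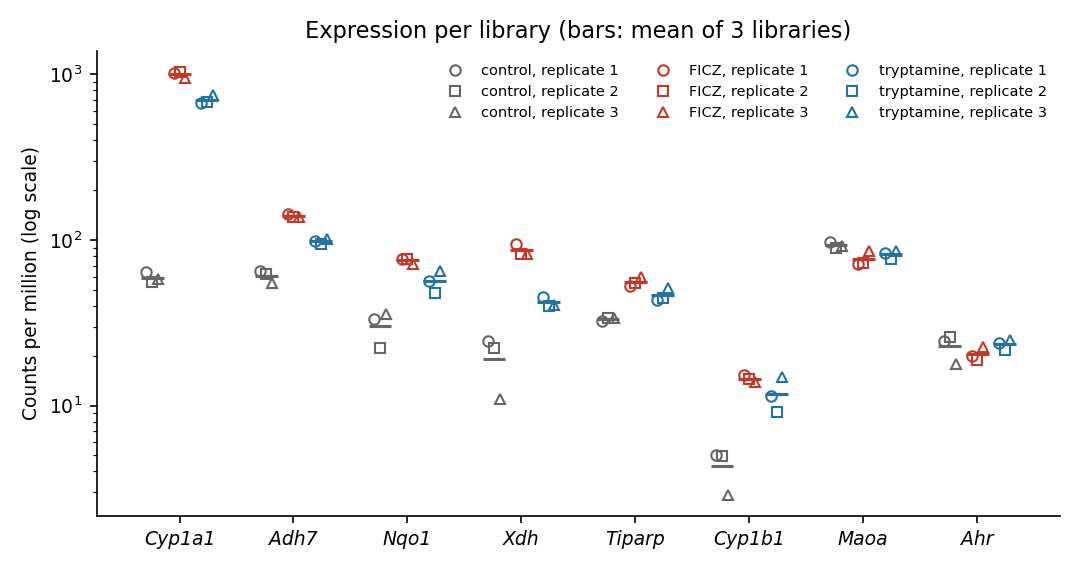
CPM on a log axis for 8 genes in each of the 9 libraries, with colours for groups, symbols for replicates and bars for the mean of 3 libraries. Cyp1a1 stands at 59.2 CPM in control, 1002.8 with FICZ and 703.2 with tryptamine, and Xdh at 19.1, 86.4 and 42.0, while Maoa and Ahr did not pass in any comparison.

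FICZ and tryptamine, both derived from tryptophan, were compared with each other at the same time but at different doses, 10 nM and 50 uM. Cyp1a1 stood at 1002.8 ± 45.2 CPM with FICZ and 703.2 ± 44.0 with tryptamine (SD, n = 3), and Xdh at 86.4 ± 7.15 and 42.0 ± 2.96 CPM. Tbc1d16 stood at 123.7 ± 9.28 and 70.2 ± 4.23, and Aldh3a1, an aldehyde dehydrogenase, at 128.1 ± 5.17 and 81.8 ± 4.24 CPM (SD, n = 3). None of these differences passed in the fit to all 9 libraries, and each passed in the fit without control replicate 3.

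In edgeR's quasi-likelihood test of the difference, 0 of 12372 genes passed, with 87 higher and 127 lower at an unadjusted p under 0.05 (377 and 371 without control replicate 3). These 214 genes with all 9 libraries are fewer than the 5% that would lie there with no difference. The fit to all 9 libraries may therefore be conservative here, and its 0 calls do not show that the treatments act alike. DESeq2's Wald test called 10 higher with FICZ and 0 lower. The log2 difference was 0.51 ± 0.089 (SE, 95% interval 0.32 to 0.71, adjusted p = 0.696) for Cyp1a1 and 1.04 ± 0.222 (SE, 95% interval 0.55 to 1.53, adjusted p = 1) for Xdh. A fit to the 6 libraries of the pair, which holds no control, called 16 genes higher with FICZ and 1 lower. Without control replicate 3, which enters only through the spread, the scaling and the filter, 15 were higher and 2 lower. There the adjusted p was 1.24e-07 for Xdh (log2 1.04 ± 0.088, SE), 4.71e-07 for Tbc1d16 (0.82 ± 0.077, SE), 1.09e-05 for Cyp1a1 (0.52 ± 0.058, SE) and 1.09e-05 for Aldh3a1 (0.65 ± 0.074, SE). Each of these 4 genes passed in 5 of 19 alternatives, with a highest adjusted p of 1. Slc2a6 (log2 2.57 ± 0.350, SE), Gbp2 (2.23 ± 0.390, SE), a guanylate-binding GTPase, Sod3 (0.84 ± 0.165, SE), the extracellular superoxide dismutase, Cyp2s1 (0.59 ± 0.10, SE), Adh7 (0.51 ± 0.067, SE) and Mpp2 (0.50 ± 0.094, SE) were also higher with FICZ there. Angpt1, an angiopoietin (log2 -0.50 ± 0.079, SE), and Alad, an enzyme of heme synthesis (-0.28 ± 0.057, SE), were lower. Over the 19 alternatives Angpt1 passed in 3 and Alad in 1, the fit without control replicate 3. The differences of Nqo1 (95% interval 0.04 to 0.79), Tiparp (0.02 to 0.51) and Cyp1b1 (-0.19 to 0.77) passed in 0 of 19 alternatives.

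As a group, the AhR target genes were higher with FICZ than with tryptamine, with 9 of 10 above 0 and a median log2 difference of 0.36 (camera adjusted p = 6.12e-20, and adjusted p = 0.00303 with an estimated correlation). Over all genes 0 of the 10 passed, and 4 were higher when adjusted over the list alone: Cyp1a1, Xdh, Aldh3a1 and Cyp2s1. These 4 passed over all genes, and 7 over the list alone, without control replicate 3. Genes of cholesterol synthesis were lower with FICZ than with tryptamine, with 0 of 13 above 0 and a median of -0.26 (camera adjusted p = 1.48e-20, and adjusted p = 0.00354 with an estimated correlation). Over all genes 0 passed, and 6 were lower when adjusted over the list alone (12 without control replicate 3, and again 0 over all genes). Dhcr7, which makes cholesterol from its last precursor, stood at 18.2 ± 1.75 CPM with FICZ and 26.7 ± 2.55 with tryptamine (SD, n = 3), a log2 difference of -0.55 ± 0.137 (SE). Mvd, mevalonate diphosphate decarboxylase, differed by -0.59 ± 0.162 (SE) and Idi1 by -0.67 ± 0.205 (SE), each of the 3 genes with an adjusted p of 1 over all genes. The NRF2 list did not pass in this comparison (camera adjusted p = 0.565), nor did the immediate early list (camera adjusted p = 0.102).

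**Figure D3:**
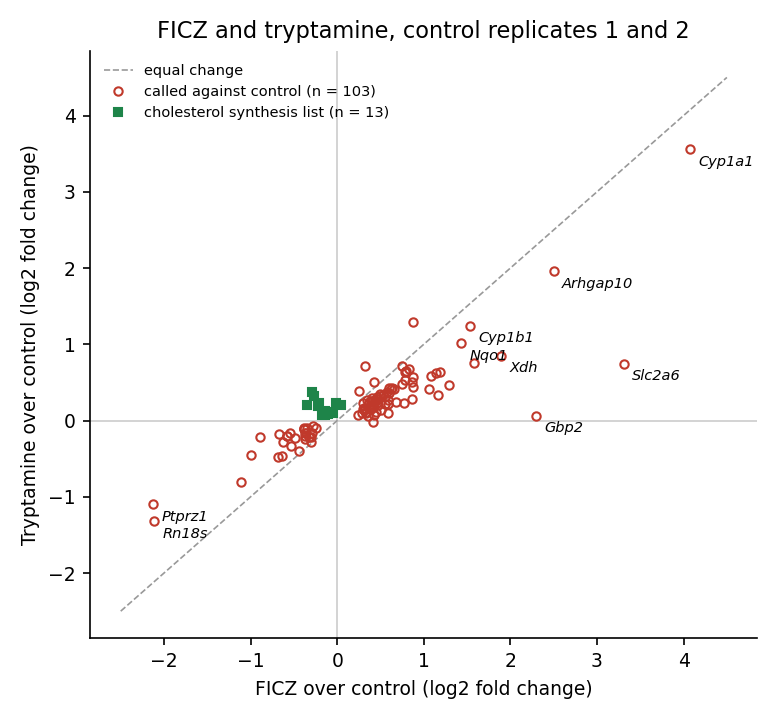
Log2 fold change over control with tryptamine (vertical axis) against that with FICZ (horizontal axis) in the fit without control replicate 3, for 103 genes that passed in at least 1 of these comparisons (circles, Cyp1a2 left out) and 13 cholesterol synthesis genes (squares); the dashed line marks equal change. All 13 squares lie above the line; the comparisons share their controls, which by itself draws the changes to the same sign.

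Genes that rose with both treatments were counted next. Cyp1a1 rose with both in the fit to all 9 libraries. When control replicate 3 was left out, 20 genes rose and 2 fell with both, Lars2 and Loxl4, and 0 moved in opposite directions. Cyp1b1, Nqo1, Xdh, Adh7, Aldh3a1, Tbc1d16, Cpox and Mpp2 were among the 20. Independent lists of these sizes would share 0.132 genes that rose, a number that takes no account of the shared controls. In 40 simulations of unchanged groups with shared controls, at most 1 gene rose with both. No gene was changed in these simulations, so few could be called at all. They cannot show how many of the 20 genes the shared controls would give. The log2 changes of the treatments correlated across genes at 0.735 with all 9 libraries and 0.666 without that control, against 0.502 and 0.610 in the simulations. Genes are not independent replicates. Because 3 controls cannot be divided so that each comparison has a pair of its own, part of this correlation comes from the shared controls. The simulations gave every library the same spread for each gene. They therefore cannot show how much of the 0.735 comes from control replicate 3. Gclm, Slc7a11 and Txlnb passed with tryptamine and not with FICZ, and their direct differences in that fit did not pass (adjusted p = 0.823, 0.563 and 0.823).

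The receptor genes themselves did not pass in any comparison. Ahr stood at 22.8 ± 4.30 CPM in control, 20.4 ± 1.87 with FICZ and 23.5 ± 1.72 with tryptamine (SD, n = 3), and Arnt, its partner, at 59.5 ± 10.1, 67.2 ± 5.26 and 64.9 ± 6.59 CPM. Maoa, the monoamine oxidase that the cells expressed, stood at 92.7 ± 3.94, 76.7 ± 8.20 and 82.4 ± 4.68 CPM (SD, n = 3), with log2 changes of -0.27 ± 0.106 (SE, adjusted p = 0.601) with FICZ and -0.17 ± 0.106 (SE, adjusted p = 0.741) with tryptamine. Maob had 3 counts in all 9 libraries and Ahrr, the AhR repressor, had 1, so no fold change is given for either. Cyp1a2, a paralog and genomic neighbour of Cyp1a1, had 1 count in the 3 control libraries, 63 in the FICZ libraries and 51 in the tryptamine libraries. Its ratio to control was 56.6 with FICZ (95% counting interval 9.79 to 2270) and 48.2 with tryptamine (8.28 to 1940). Against Cyp1a1 it made 0.411 counts per 1000 in control (95% interval 0.0104 to 2.29), 1.38 with FICZ (1.06 to 1.77) and 1.68 with tryptamine (1.25 to 2.21). With 1 count in control, these shares cannot be compared between control and treated cells.

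The remaining 13 tested lists passed camera in none of the 3 comparisons with all 9 libraries. With fry, the cell cycle was lower with FICZ than with control (adjusted p = 0.00335) and than with tryptamine (adjusted p = 0.03). These shifts were small, with median log2 differences of -0.082 and -0.031, and 0 of 20 members passed over the list alone in either comparison. Tryptophan and monoamine metabolism was lower than control by fry with FICZ (adjusted p = 0.0325) and with tryptamine (adjusted p = 0.0372). Without control replicate 3, fry kept the cell cycle (adjusted p = 0.00966 and 0.048) and lost tryptophan and monoamine metabolism (adjusted p = 0.138 and 0.203). Without control replicate 3, camera called p53 targets for FICZ against control (adjusted p = 0.0493, and adjusted p = 0.184 with an estimated correlation) and the inflammatory response for FICZ against tryptamine (adjusted p = 0.0444, and adjusted p = 0.186 with an estimated correlation). Fatty acid and lipid metabolism was also called there for FICZ against tryptamine (adjusted p = 0.0227, and adjusted p = 0.173 with an estimated correlation). With all 9 libraries the lowest camera adjusted p was 0.0618 for the inflammatory response (FICZ against tryptamine), in which Tnfaip2 rose with FICZ over control. It was 0.0746 for hepatocyte genes (FICZ against control), where Alb had a log2 change of -0.26 ± 0.097 (SE). Tryptophan and monoamine metabolism reached 0.113 for tryptamine against control (0.269 with an estimated correlation; 0.042 after each library's trend with transcript length was removed, where no correlation was estimated), fatty acid and lipid metabolism 0.182 and the AhR complex and cofactors 0.213. The cell cycle, p53 targets, the circadian clock and other xenobiotic metabolism each reached 0.293, the ER stress and amino acid response 0.408 and the hypoxia response 0.467. For markers of other cell types, the lowest camera adjusted p was 0.594 for bile duct epithelium and 0.894 for fibroblasts and stellate cells. Members of the last list moved apart with FICZ over control. Adjusted over the list alone, Col3a1 was higher (log2 0.53 ± 0.137, SE) and Dcn lower (-0.31 ± 0.091, SE), and Col3a1 rose over all genes without control replicate 3 (log2 0.39 ± 0.093, SE, adjusted p = 0.0453). Blood and endothelial markers had too few measured members, and Lyz2, a macrophage marker, stood at 13.7 ± 2.50 CPM in control and 12.8 ± 0.154 with FICZ (SD, n = 3). Krt7, a bile duct keratin, was high in every group, at 1056.8 ± 229.6 CPM in control and 877.1 ± 30.3 with FICZ (SD, n = 3). The inflammatory list had a median of -0.19 for FICZ against control while camera pointed up (adjusted p = 0.858). Without control replicate 3 this median was -0.007 (camera adjusted p = 0.263).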

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

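Both tests of transcript length below, and the fits with library quality weights or with the length trend removed, were chosen only after the results they bear on had been seen. The other tests were set before their outcome was known.

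The direct comparison of FICZ with tryptamine differed for the list of AhR target genes, whose median log2 difference was 0.356, and for cholesterol synthesis, with a median of -0.255. For the AhR list the median ranged from 0.342 to 0.51 over the 9 fits that left out 1 library. The highest camera adjusted p of these fits was 1.76e-13 at the preset correlation. With an estimated correlation, the adjusted p was 0.00303 with all libraries and 0.00288 without control replicate 3. The other fits that left out 1 library were not tested with an estimated correlation.

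Control replicate 3 stood apart from the other 8 libraries, and the design gives no biological explanation that could be tested. GC content and lower depth are argued against as the cause. The partial correlation across genes of its departure with GC content, given length, was 0.021. The other libraries had -0.389 to 0.331, with tryptamine replicates 2 and 3 at 0.331 and -0.389 and FICZ replicate 3 at -0.334. GC content was not tested as a cause of the differences between FICZ and tryptamine. Thinned to the total count of control replicate 3 over the genes tested, no other library reached an SD of the departure above 0.312. Control replicate 3 had 0.697. Its departure followed transcript length, with a partial Spearman correlation across genes of -0.69 given GC content, while the other libraries had -0.177 to 0.119. GC content was known for 88.4% of the genes tested. A difference in RNA quality or library preparation that acts through transcript length may therefore lie behind this library, but the labels record neither and the trend was seen before it was tested.

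Cholesterol synthesis genes were lower with FICZ than with tryptamine. Removing the length trend of every library left the median at -0.265. Leaving out 1 library at a time left the median at -0.232 or farther from 0. These medians argue against length and against a single library as the cause. The highest camera adjusted p without 1 library was 2.53e-14 at the preset correlation. With an estimated correlation, the adjusted p was 0.00354 with all libraries and 0.00288 without control replicate 3. The other fits that left out 1 library were not tested with an estimated correlation. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split (1 of 10 as far from 0) had a median size of 0.255 and the highest other had 0.17. A difference between the treatments in sterol metabolism may explain it, as a hypothesis found and tested on the same data, since 0 of 13 genes passed singly over all genes.

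Genes that rose with FICZ were also higher with tryptamine, and both comparisons share their controls. To separate them, the 50 genes with the largest rise in FICZ replicate 1 over control replicate 1 were read as tryptamine over control replicate 2. Their median log2 difference was 0.214, above the 95% range of -0.059 to 0.058 of random sets matched on expression, and 37 of 50 were higher. The 6 choices run, each FICZ library with control replicates 1 and 2 in either role and none with control replicate 3, lay above their range, with medians of 0.173 to 0.214, which argues against shared controls as the whole cause. A response to tryptamine that overlaps with that to FICZ may account for the rest. All 6 choices share the tryptamine libraries and genes such as Cyp1a1, Xdh and Nqo1, so they are not separate tests. Without control replicate 3, simulated unchanged groups with shared controls gave a covariance across genes of 0.0337, against 0.0583 measured. With all libraries these values were 0.0348 and 0.0706, but the simulations gave every library the same spread for each gene. They therefore cannot show how much of the 0.0706 comes from control replicate 3.

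For the counts of genes called, the 10 splits of the 6 libraries of each pair are too few for a share under 0.05. In FICZ against control the real split called 14 genes and the highest other 0 (1 of 10 splits as large), and in tryptamine against control 1 gene and 0 (1 of 10). For FICZ against tryptamine the real split called 0 and the highest other 0 (10 of 10). At an unadjusted p under 0.05, the real split gave 1004 genes for FICZ against control and the highest other 513. For tryptamine against control these numbers were 637 and 750, and for FICZ against tryptamine 214 and 273, so at that threshold other splits gave more genes than the real split.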

How the results depend on the processing

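Sums over transcripts, library quality weights, removal of the length trend and the list tests without control replicate 3 were chosen after seeing the data. Of 1176 values of named genes under an alternative, 992 kept their side of the threshold, 115 moved past it, 69 no longer passed and 0 of those called changed sign. The genes called for FICZ against control (14) became 54 with DESeq2's Wald test, 26 with no filter, 2 with the 6 libraries of the pair, 4 at an adjusted p under 0.01, 9 with transcripts tested singly, 4 with sums over transcripts, 114 with quality weights and 51 with the length trend removed. For tryptamine against control (1) there were 12 with the Wald test, 2 with no filter, 2 with sums, 19 with quality weights and 6 with the length trend removed. For FICZ against tryptamine (0) the Wald test gave 10, the 6 libraries 17, quality weights 18 and the length trend 5. Calls shared by both treatments (1) were 10, 2, 17 and 6 with the Wald test, no filter, quality weights and the length trend. The fits without 1 library gave 4 to 101 genes, 1 to 25, 0 to 17 and 1 to 22 shared calls, the highest each without control replicate 3 and the lowest for FICZ against control without a FICZ replicate. Camera's list calls (8 of 51) became 6 with an estimated correlation and 13 with the length trend removed. Without control replicate 3 they were 14 of 54 (7 with an estimated correlation). Fits to a pair or without a library hold fewer samples, and no filter tests more genes. Fewer samples by themselves would lower the counts. The rise without control replicate 3 goes with a smaller spread. The square root of the common dispersion was 0.156 with that library and 0.0748 without it. Quality weights gave that library a weight of 0.078. The cause of the other changes was not tested.

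With the replicate number as a term, 4 genes passed for FICZ against control. Departures of libraries with equal numbers correlated across genes at -0.058 to 0.116 and those with other numbers at -0.122 to 0.102. Equal-number pairs of FICZ and tryptamine had 0.054, 0.044 and 0.116, and those with a control had -0.058 to 0.041. These values cannot settle whether equal numbers share a day. The alternatives for pseudocounts and minimum expression were not run, since the tables hold counts. Depth limits Cyp1a2, Ahrr and Maob.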

Other observations

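The genes named here from the fit without control replicate 3, and the list tests in that fit, were chosen after their values were seen.

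Further genes rose with FICZ when control replicate 3 was left out. Por, the electron donor of microsomal cytochromes P450, rose by log2 0.51 ± 0.076 (SE), Gsta4, a glutathione transferase, by 0.78 ± 0.141 (SE), Sod3 by 1.17 ± 0.193 (SE) and the Ugt1a locus by 0.86 ± 0.193 (SE, named Ugt1a2 in the tables). Gbp2 rose by 2.29 ± 0.452 (SE), Stat3 by 0.35 ± 0.071 (SE) and Ddx58, a sensor of viral RNA, by 0.60 ± 0.091 (SE). Met, the receptor of hepatocyte growth factor, rose by 0.50 ± 0.065 (SE) and the growth factor Nrg1 by 0.66 ± 0.082 (SE). With tryptamine, Met (0.35 ± 0.065, SE), Nrg1 (0.41 ± 0.082, SE) and Ddx58 (0.42 ± 0.091, SE) rose as well, while Gbp2 had a log2 change of 0.06 ± 0.522 (SE, adjusted p = 0.993) and differed between the treatments (log2 2.23, adjusted p = 0.00609; 0.00166 to 1 over 19 alternatives).

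Genes that fell with FICZ in the same fit included Fhl1 (log2 -0.68 ± 0.131, SE), Angpt1 (-0.67 ± 0.087, SE), Rasgrp3 (-0.89 ± 0.216, SE), Odc1, the first enzyme of polyamine synthesis (-0.36 ± 0.066, SE), and Alad (-0.38 ± 0.063, SE). The falls of Rn18s (-2.11), Ptprz1 (-2.13) and Lars2 (-1.11) rest on control replicate 2. Rasgrp3 was highest in control replicate 1, at 11.3 CPM against 6.95 and 7.59 in control replicates 2 and 3; its log2 change without that library was -0.56, and it passed in 2 of 19 alternatives. Rn18s, the 18S ribosomal RNA, stood at 1856.5 CPM in control replicate 2 against 346 and 332.8 in control replicates 1 and 3, and the log2 changes without control replicate 2 were -0.41, -0.50 and -0.34.

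Without control replicate 3, fatty acid and lipid metabolism passed camera as lower with FICZ than with control (median log2 -0.10, adjusted p = 0.00494, and adjusted p = 0.121 with an estimated correlation), with Plin2, a lipid droplet protein, at -0.30 ± 0.066 (SE). With all 9 libraries this list had a median of 0.06 with 8 of 11 members above 0 (adjusted p = 0.93), against 1 of 11 without that control, so its direction turned with 1 library. The same list was lower with FICZ than with tryptamine in that fit (adjusted p = 0.0227, and adjusted p = 0.173 with an estimated correlation). For tryptamine against control, the immediate early list passed (median 0.10, adjusted p = 0.00633, and adjusted p = 0.508 with an estimated correlation). Cholesterol synthesis had a median of -0.14 with FICZ over control there (adjusted p = 0.00494, and adjusted p = 0.143 with an estimated correlation). With all 9 libraries its median was -0.07 and it did not pass camera (adjusted p = 0.198).

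The authors' tables give 7345 transcripts of 2022 genes with an adjusted p under 0.05 for FICZ against control, 3121 of the transcripts higher and 4224 lower. For tryptamine against control they give 1890 transcripts of 597 genes, and for FICZ against tryptamine 104 transcripts of 25 genes. The deposited lists of 81 and 22 genes equal those with a transcript at an adjusted p under 0.05 and a log2 fold change above 1.0 in these tables. Their mean log2 fold change for Cyp1a1 is 4.02 with FICZ and 3.51 with tryptamine. Of 77 listed FICZ genes tested here, 12 passed with all libraries and 24 without control replicate 3, and 63 had a lower log2 change without it. The 53 FICZ genes that did not pass without control replicate 3 had a median log2 change of 0.13 there. Their transcripts used here had a median length of 5981 nt, against 2880 nt for all genes tested. All listed FICZ genes tested had a median of 0.504 with all libraries and 0.334 without control replicate 3. A listed gene needs only 1 transcript past both thresholds, while here the transcript with the highest mean count stands for the gene. The values here may therefore be of another transcript. Of 21 listed tryptamine genes tested, 1 passed with all libraries and 7 without that control, and 16 had a lower log2 change without it.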
